A study of Homo sapiens with 12 samples.

How the data were processed

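RNA was measured by sequencing in 12 libraries from 2 human colorectal cancer cell lines, SW480 and DLD1, grown with or without added lactate. Per the labels, each line had 3 control and 3 lactate-treated libraries, described as biological replicates. The labels give neither the dose of lactate nor the time of treatment. The deposited table holds whole-number read counts per gene symbol, 1 column per library, with no normalization. Reads were aligned with HISAT2 to GRCh38 per the submitters' processing notes. The HISAT2 version, the counting tool, the annotation and the strand setting are not given in the sources used here. All 12 columns matched 1 library each by its title, and 0 columns were left unused.

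The table names 54261 gene symbols. Of these, 45971 matched a current RefSeq symbol, 1854 matched through 1 unambiguous older name, and 6436 were not matched. The unmatched symbols held 0.609% of the counts. They stayed in the tests. Positions are those of RefSeq on GRCh38.p14, with start and end of the gene. Total counts per library ran from 12302311 to 22662063. A simulation was used to see what this depth and replication could show. Among 17272 tested genes of simulated data with 67 genes changed 2-fold in each line, 76.1% were recovered in SW480 and 76.1% in DLD1. For 67 genes changed 1.5-fold the shares were 32.8% and 34.3%. The simulated spread of each gene was the same in all groups, so similar shares in both lines are built in. Some real DLD1 controls lay further from their group than any other library, so the shares may not hold for DLD1. Over the whole simulation, with 200 genes changed 1.5-fold, 2-fold or 4-fold in each line, 7 and 4 unchanged genes were called. A list shifted by 0.5 on the log2 scale was called and 0 other lists were. Simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely.

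Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 17572 genes. Libraries were scaled by TMM. One quasi-likelihood model with robust dispersions and 1 mean per group was fitted over all 12 libraries. Its two-sided tests gave the lactate effect in each line, the difference of the effects (DLD1 minus SW480) and the difference between the control groups. A gene is called where edgeR's Benjamini-Hochberg adjusted p is under 0.05. Fold changes are log2 values. Their standard error (SE) was derived from the test, as the absolute log2 fold change over the square root of its F statistic. Levels are counts scaled to the total of the library (CPM), given as mean ± standard deviation (SD) over the n = 3 libraries of a group. Overlaps of called genes were tested with Fisher's exact test, two-sided.

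A set of 40 gene lists with 909 members was fixed before the data were examined. Afterwards, older names of the 13 mitochondrially encoded genes were added so that they matched the table. A list was tested when at least 5 of its members were, which held for 37 lists. Endothelial markers had 3 tested members, erythroid markers 0 and small structural RNAs 4, so these lists were not tested. The test was camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry.

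The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule took several sets of genes. One set was, per line and direction, the 10 called genes with the largest fold change, a mean of at least 5 CPM in the higher group and no overlap between the 3 control and 3 lactate libraries. Another was up to 10 genes called in both lines with the same sign, under the same conditions. It also took up to 4 members of each list with the smallest p among those called, and up to 8 genes with the smallest p among those called for the difference between lines, with a mean of at least 5 CPM in some group. Pseudogenes and unnamed loci were left out of the first set. A set of 10 genes, among them LDHA, HCAR1 and TXNIP, was named whatever their p, and CDH1, VIM, EPCAM, CDX2, KRT20 and LGR5 were named for the lines.

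The alternatives were median-of-ratios and upper quartile scaling, no filter, a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, replicate number as a block, each line fitted alone, an absolute log2 fold change of at least 1, and leaving out each library in turn. After the data had been seen, a removal of the trend along transcript GC content and length within each library was added. It used natural splines with 5 degrees of freedom, fitted over genes with a mean log2 CPM of at least 1, and entered the model as offsets. It also removes any effect of lactate that follows GC content. GC content was known for 87.7% of tested genes. On simulated data with such a trend in 1 DLD1 control library, it raised the share of 200 changed genes recovered from 64.5% to 72.5%, with 8 and 10 unchanged genes called among 17248. The list tests of the difference between lines and of the control groups, and a correlation over expressed genes alone, were also added then. In comparing settings, a sign that flipped where neither setting passed the threshold was not counted as a change. Results that left out a library were fitted with the spread pooled over all groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.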

Results

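The series measured gene expression in SW480 and DLD1, 2 established human colorectal cancer cell lines, after lactate treatment, with 3 control and 3 lactate libraries per line. Lactate is the product of glycolysis that cells release and take up again. In the order of replicates 1 to 3, the SW480 controls held 15543396, 12302311 and 17286493 counts. The SW480 lactate libraries held 16030940, 19354661 and 14049106 counts. The DLD1 controls held 20150229, 14928364 and 19203730 counts, and the DLD1 lactate libraries 16517364, 19389983 and 22662063. Transcripts encoded in mitochondrial DNA took 4.93% ± 0.239 (SD, n = 3) of the counts in SW480 controls and 3.60% ± 0.159 after lactate. In DLD1 they took 5.06% ± 0.175 and 5.05% ± 0.0694.

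The libraries that differed most from the others of their group were DLD1 controls. Over 12028 genes with a known GC content, the log2 difference of a library from the other 2 of its group had an SD of 0.537 for DLD1 control 2 and 0.442 for DLD1 control 3. The highest value among the SW480 and DLD1 lactate libraries was 0.261. These differences followed transcript GC content across genes, with Spearman's rho -0.78 for control 2 and 0.81 for control 3. Smaller trends ran in opposite directions in other groups, at rho -0.60 for SW480 lactate 3 and 0.49 for SW480 lactate 1, and at -0.51 for DLD1 lactate 2 and 0.45 for DLD1 lactate 3. Because each library is compared with the other 2 of its group, opposite directions within a group follow in part from the comparison itself. The lactate fold changes in DLD1 followed it too, at rho 0.69 across genes, against 0.03 in SW480. The rho in DLD1 was 0.29 without control 2 and 0.78 without control 3. Genes are not independent replicates, so these rho describe the libraries and carry no p.

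**Figure D1:**
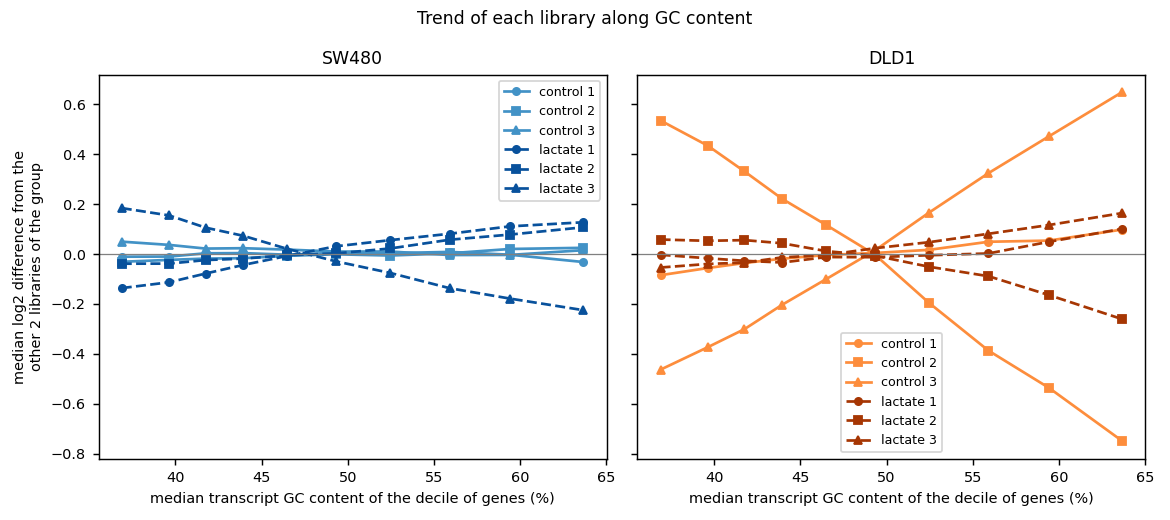
Median log2 difference of each library from the other 2 of its group (vertical axis) against the median transcript GC content (%) of 10 equal groups of genes (horizontal axis), 1 line per library. DLD1 control 2 (rho -0.78) and DLD1 control 3 (rho 0.81) run in opposite directions, which the comparison within a group brings about in part.

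The first comparison asked which genes responded to lactate in SW480. The gene with the largest rise was HSPA6, a stress-inducible member of the HSP70 chaperones, from 0.403 ± 0.0644 to 40.0 ± 3.26 CPM. NDRG1, a gene induced by hypoxia and stress, rose from 185 ± 64.7 to 1139.7 ± 151 CPM. The cytokine genes IL24, CSF3 and IL1B rose as well, by 2.94, 2.61 and 2.21 on the log2 scale. So did ANKRD37 (2.50), MN1 (2.39), CYP1A1 (2.39), a target of the aryl hydrocarbon receptor, and the keratin gene KRT15 (2.15). Among genes that fell, OTOGL changed by -2.08 ± 0.21, GJA5, which encodes a gap junction protein, by -1.48 ± 0.15, FSTL4 by -1.48 ± 0.25, ZNF596 by -1.33 ± 0.17, DOK3 by -1.32 ± 0.26 and NCOA5, a nuclear receptor coactivator, by -1.29 ± 0.13 (log2 ± SE). The mitochondrial tRNA genes TRNP and TRNY changed by -2.39 ± 0.45 and -2.04 ± 0.59, and the noncoding RNA genes THRIL and C5orf66 (now PITX1-AS1) by -1.73 ± 0.54 and -1.38 ± 0.34. HSPA6 lies on chromosome 1, 161524540 to 161526894, and NDRG1 on chromosome 8, 133237175 to 133297252.

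In edgeR's quasi-likelihood test, 2183 of 17572 genes were called in SW480, of which 1201 rose and 982 fell, and 515 changed at least 2-fold (349 up, 166 down). The adjusted p was 4.72e-08 for HSPA6, with a log2 fold change of 6.59 ± 0.31, and 2.84e-05 for NDRG1, with 2.62 ± 0.23. The control and lactate libraries did not overlap for 41.0% of genes, against 10% given by chance. Of the genes named above, TRNY, THRIL and C5orf66 lost their call without some libraries and the others held without any 1 of the 12. TRNY held only without SW480 control 3, SW480 lactate 1, DLD1 control 2 or DLD1 control 3, and had adjusted p of 0.0503 to 0.139 without each other library. THRIL held only without SW480 lactate 1 or DLD1 control 3, with 0.0513 to 0.189 otherwise, and had 0.0516 with the GC content and length trend removed. With SW480 fitted alone TRNP, TRNY and THRIL had adjusted p 0.0642, 0.180 and 0.175. C5orf66 had adjusted p 0.0591 without SW480 control 1, 0.0712 without control 2, 0.0937 without lactate 2 and 0.0730 without lactate 3. The number of calls was 689 without SW480 control 1, 1219 without control 3, 855 (582 up, 273 down) without lactate 2, 1211 (804 up, 407 down) without lactate 3 and 4347 without DLD1 control 2. It was 4862 with the GC content and length trend removed (2154 of the 2183 among them) and 4783 with SW480 fitted alone.

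Several lists rose in SW480. Of 27 immediate early genes, the first to respond to growth and stress signals, 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.77. PHLDA1 rose from 257 ± 47.1 to 812 ± 44.6 CPM, and CYR61 (now CCN1), DUSP5 and KLF6 rose by 1.36, 1.71 and 0.92. The list's adjusted p in camera was 1.13e-15, and its adjusted p = 0.0845 with an estimated correlation. Of 26 hypoxia (HIF) targets outside glycolysis, 18 rose and 0 fell (20 and 1 adjusted over the list alone), with a median of 0.68. VEGFA, which encodes a growth factor of blood vessels, rose from 196 ± 30.8 to 424 ± 49.6 CPM. The list had adjusted p 4.57e-14 in camera, and adjusted p = 0.0845 with an estimated correlation. Of 19 glycolysis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone). The hexokinase gene HK2 rose from 172 ± 28.5 to 441 ± 44.5 CPM, and the glucose transporter gene SLC2A3 rose by 1.30. Glycolysis had an adjusted p of 8.90e-05 in camera, and adjusted p = 0.346 with an estimated correlation.

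Of 27 NF-kB and inflammatory genes, 14 rose and 0 fell in SW480 (15 and 1 adjusted over the list alone), with a median of 0.34. They included IL1A (1.22), the chemokine gene CCL20, from 29.1 ± 7.94 to 81.8 ± 10.8 CPM, and TNFAIP3 (0.68), a feedback inhibitor of NF-kB. The adjusted p was 2.06e-07, and adjusted p = 0.0845 with an estimated correlation. TGF-beta and YAP targets rose in 9 of 22 (10 adjusted over the list alone), with adjusted p 4.20e-05, and adjusted p = 0.0845 with an estimated correlation. Integrated stress response (ATF4) targets rose in 9 and fell in 2 of 30 (12 and 4 adjusted over the list alone). PPP1R15A rose by 0.87 and the tRNA synthetase gene WARS, whose call was lost without 2 libraries, changed by -0.45. WARS had adjusted p 0.0520 without SW480 lactate 2 and 0.0542 without SW480 lactate 3. The list's adjusted p was 0.0226, and adjusted p = 0.0845 with an estimated correlation. Lysosome and autophagy genes rose in 6 and fell in 1 of 27 (9 and 2 adjusted over the list alone), with the cholesterol exporter gene NPC1 at 1.06. That list had adjusted p 0.00557, and adjusted p = 0.0845 with an estimated correlation. Among p53 targets, 4 of 21 rose (6 adjusted over the list alone), including CDKN1A (0.69), an inhibitor of the cell cycle. Camera gave them adjusted p 0.00586, and adjusted p = 0.0861 with an estimated correlation. Of the 8 thioredoxin-interacting protein family genes (MondoA targets), TXNIP rose from 666 ± 140.3 to 1285 ± 246 CPM and 7 were not called (1 called adjusted over the list alone). That list's adjusted p was 0.0421, and adjusted p = 0.111 with an estimated correlation. It was 0.0759 without SW480 control 3, 0.0576 without lactate 1, 0.0526 without lactate 2 and 0.0663 with the GC content and length trend removed.

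Cell division genes were lower after lactate in SW480. Of 35 genes of G2/M and mitosis, 27 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of -0.53. The kinesin gene KIF20A changed by -1.05, the cyclin gene CCNB1 by -0.98 and the kinase gene PLK1 by -1.07. The list had adjusted p 1.48e-20 in camera, and adjusted p = 0.0845 with an estimated correlation. Of 33 DNA replication and G1/S genes, 17 fell and 0 rose (25 and 0 adjusted over the list alone), among them the helicase gene MCM3 (-0.75). Camera placed them at adjusted p 4.05e-14, and adjusted p = 0.0845 with an estimated correlation. Of 28 ribosome biogenesis and MYC targets, 13 fell and 1 rose (19 and 1 adjusted over the list alone), with NOP56 at -0.89. Their adjusted p was 9.67e-10, and adjusted p = 0.0845 with an estimated correlation.

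Mitochondrially encoded genes fell in SW480, 10 of 13 (12 adjusted over the list alone), with a median of -0.55. COX3, a subunit of cytochrome c oxidase, changed from 7769 ± 768 to 4254 ± 77.2 CPM. Copies of these genes in nuclear DNA share their sequence. The adjusted p was 4.77e-09, and adjusted p = 0.0845 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes fell in 2 of 47 (0 adjusted over the list alone), with adjusted p 2.70e-04, and adjusted p = 0.542 with an estimated correlation. Both calls were fragile. ATP5G3 (now ATP5MC3) held without DLD1 controls 1, 2 or 3 and DLD1 lactate 1 or 2, and had adjusted p of 0.0502 to 0.174 without each other library and 0.125 with the GC content and length trend removed. ATP5A1 (now ATP5F1A) held only without DLD1 control 2 or 3, with 0.0511 to 0.199 otherwise, and had 0.0518 with median-of-ratios scaling, 0.0727 without a filter and 0.0822 with replicate blocks. Endoplasmic reticulum chaperones fell in 7 of 19 (9 adjusted over the list alone), including HSP90B1 (-0.71). As a list they had adjusted p 3.17e-05, and adjusted p = 0.111 with an estimated correlation. NRF2 targets fell in 9 and rose in 2 of 24 (12 and 2 adjusted over the list alone). The antioxidant gene NQO1 changed by -0.61 and the ferritin gene FTH1, which has many pseudogenes, rose by 0.75. Tested together they had adjusted p 8.65e-04, and adjusted p = 0.111 with an estimated correlation. Heat shock response genes fell in 5 of 16 and HSPA6 rose (7 and 1 adjusted over the list alone), so that the median was -0.22 and the mean 0.21. The chaperonin gene HSPD1 changed by -0.63. That list's adjusted p was 0.0360 in the downward direction, and adjusted p = 0.256 with an estimated correlation. It was 0.0868 without SW480 control 1, 0.0835 without control 3, 0.0899 without lactate 1 and 0.0523 without lactate 2.

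Among genes that handle lactate itself, 4 of 19 were called in SW480, with PDK3 and PDK1 up and LDHB and PDHB down. LDHA, the lactate dehydrogenase subunit of muscle type, stood at 3591 ± 129 and 4045 ± 47.9 CPM (adjusted p 0.218), and was called with the GC content and length trend removed (log2 0.23, adjusted p 0.0200) and in DESeq2 (0.0429). PDK3 and PDK1, kinases that hold pyruvate dehydrogenase inactive, rose from 74.4 ± 4.90 to 118 ± 8.40 CPM and from 106 ± 7.79 to 146 ± 11.3 CPM (adjusted p 6.94e-04 and 0.00985). PDK3 held without any 1 of the 12 libraries, and PDK1 had adjusted p 0.0731 without SW480 control 1. PDHB, a subunit of that dehydrogenase, changed by -0.42 ± 0.10 (adjusted p 0.0155), with 0.104 without SW480 control 1, 0.0638 without control 3, 0.0649 without lactate 1, 0.0809 without lactate 2 and 0.0646 without lactate 3. LDHB, the heart-type subunit of lactate dehydrogenase, fell from 1005 ± 46.7 to 762 ± 37.2 CPM (log2 -0.40 ± 0.10, adjusted p 0.0196). That call was lost without SW480 control 1 (adjusted p 0.104), control 3 (0.0505), lactate 2 (0.0848) and lactate 3 (0.0927). The monocarboxylate transporter genes SLC16A1 and SLC16A3 had adjusted p 0.843 and 0.385, and ARRDC4 and PDK4 0.289 and 0.544. With the GC content and length trend removed ARRDC4, a MondoA target, was called in both lines (log2 0.25, adjusted p 0.0455 in SW480; log2 0.57, 0.00169 in DLD1), and in DLD1 also without DLD1 control 2 (0.0162). SLC16A3 was called in SW480 with the line fitted alone (0.0208) and without a filter (0.0479). In DLD1 SLC16A1 and SLC16A3 were called without DLD1 control 3 (0.0227 and 0.00653) and without a filter (both under 0.05). HCAR1, the gene of a lactate receptor, had too few counts to be tested. The list of lactate transport, sensing and conversion had 2 members up and 2 down of 19 (2 and 3 adjusted over the list alone; camera adjusted p 0.664). In DLD1 1 of the 19 was called, LDHD, a dehydrogenase of D-lactate, from 0.769 ± 0.347 to 2.30 ± 0.320 CPM (adjusted p 0.0268; list 0.831). LDHD had adjusted p 0.140 without DLD1 control 1, 0.146 without lactate 1, 0.0609 without lactate 2, 0.107 without lactate 3, 0.0507 without SW480 lactate 3 and 0.0537 in limma-voom.

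**Figure D2:**
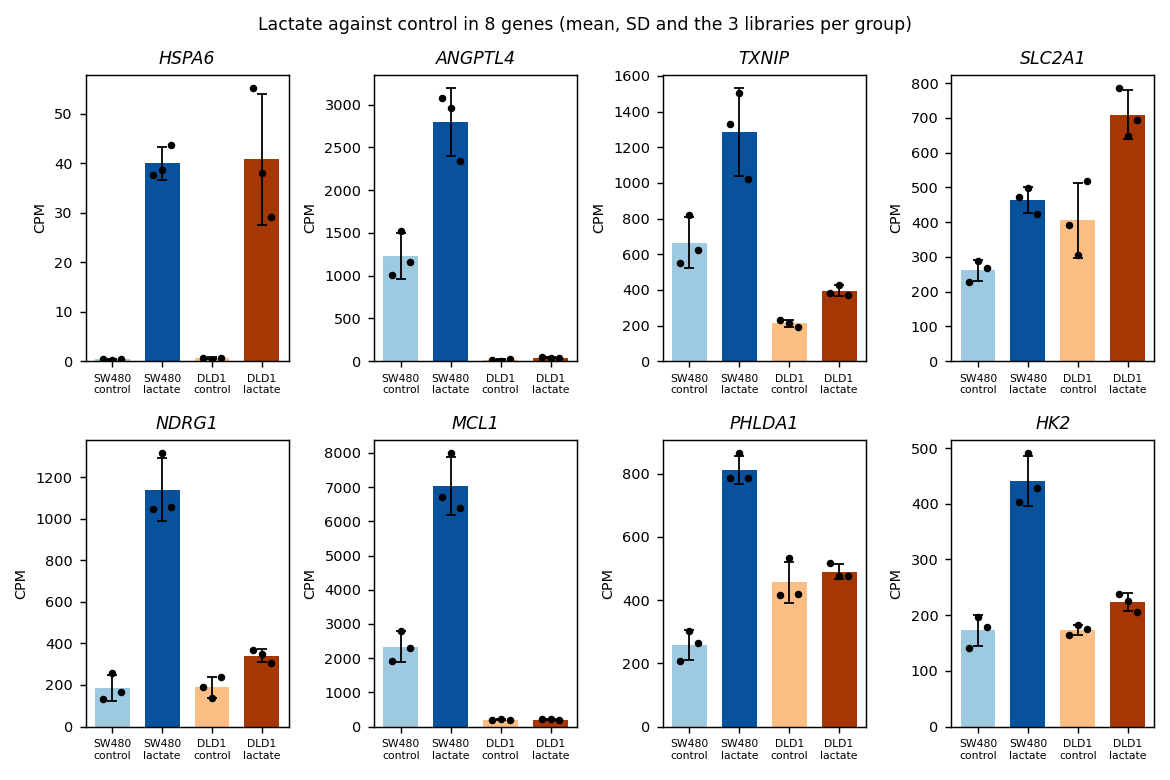
CPM (vertical axes, from 0) of 8 genes in the 4 groups, with 1 point per library, bars at the mean and error bars of 1 SD (n = 3). HSPA6 rose in both lines, to 40.0 CPM in SW480 and 40.8 CPM in DLD1, whereas MCL1 went from 2336 to 7031 CPM in SW480 and from 204 to 202 CPM in DLD1.

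The same question was asked in DLD1. HSPA6 again had the largest rise, from 0.590 ± 0.227 to 40.8 ± 13.3 CPM. CTGF (now CCN2), a matricellular protein gene and target of TGF-beta and YAP, rose by 1.52 on the log2 scale, and ANGPTL4, an inhibitor of lipoprotein lipase, from 14.8 ± 5.98 to 40.8 ± 7.39 CPM. The immediate early gene FOS rose by 1.41, the creatine transporter gene SLC6A8 by 1.29 and ALDOC, an aldolase of glycolysis, by 1.20. PSCA (1.42), the alkaline phosphatase gene ALPP (1.31), which has close paralogs, and the protease gene KLK7 (1.19) were also among the largest rises. In DLD1 controls CTGF, FOS and PSCA were low, at 1.71 to 1.98, 1.98 to 3.17 and 1.12 to 2.82 CPM. The 8 genes that fell included 6 chemokine genes. CXCL8 changed from 124 ± 52.8 to 53.9 ± 3.62 CPM, CCL20 from 77.7 ± 14.6 to 36.5 ± 3.43, CXCL1 from 75.9 ± 5.47 to 40.9 ± 3.07, CXCL3 from 93.3 ± 4.36 to 53.4 ± 5.43, CXCL5 from 4313 ± 1047 to 2497 ± 74.0 and CXCL2 from 42.8 ± 1.14 to 25.5 ± 1.97. CXCL1, CXCL2 and CXCL3 are near-identical paralogs that can share reads. The others were AMD1, an enzyme of polyamine synthesis (-0.67), and SEC11C, a signal peptidase subunit (-0.62). CXCL8 lies on chromosome 4, 73740569 to 73743716, and CCL20 on chromosome 2, 227813842 to 227817556.

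In edgeR's quasi-likelihood test 67 of 17572 genes were called in DLD1, with 59 up and 8 down, and 31 at least 2-fold (29 up, 2 down). An unadjusted p under 0.05 was reached by 3253 genes, and 18.9% of genes did not overlap between the groups, against 10% by chance. The adjusted p was 3.95e-08 for HSPA6 (log2 6.04 ± 0.28), 8.20e-04 for CXCL1 (-0.89 ± 0.09) and 0.0298 for CXCL8 (-1.20 ± 0.22). With the GC content and length trend removed the log2 fold changes of CXCL8, CXCL5, AMD1 and SEC11C in DLD1 were smaller, at -0.79, -0.49, -0.41 and -0.41, and all 4 were called. Without DLD1 control 2 that of CXCL8 was -0.81. In limma-voom 7 of the 36 named calls were lost, among them CXCL8 (adjusted p 0.0516), PSCA (0.0640), SNAI1 (0.0630), FOSB (0.0537) and ANKRD1 (0.0991). HSPA6 and CXCL1 were the named calls that held without any 1 of the 12 libraries. These fits kept the spread pooled over all groups. With DLD1 fitted alone the 6 chemokine genes were not called, with adjusted p from 0.187 (CXCL1) to 0.313 (CXCL8). Of 36 named calls, 2 held without DLD1 control 1, 5 without lactate 1, 8 without lactate 2 and 8 without lactate 3. Without these libraries the adjusted p of the others lay between 0.0539 and 0.274. All 36 held without control 2 and without control 3. Between 20 and 28 held without 1 SW480 library, 28 without control 1, 24 without control 2, 23 without control 3, 22 without lactate 1, 22 without lactate 2 and 20 without lactate 3, with adjusted p between 0.0501 and 0.107 for the rest.

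The count of genes in DLD1 moved widely. It was 3 without DLD1 control 1, 149 without control 2, 3791 without control 3 (1881 up, 1910 down), 7 without lactate 1 (3 up, 4 down), 12 without lactate 2 and 11 without lactate 3. Without SW480 control 2 or control 3 it was 42 each, and without SW480 lactate 1, 2 or 3 it was 32, 35 and 30. With the GC content and length trend removed, 561 genes were called, 310 up and 251 down, including all 67. DESeq2 called 684 (339 up, 345 down) and kept 58 of the 67, and without a filter 855 were called (556 up, 299 down). With replicate blocks 184 were called, and with DLD1 fitted alone 1 was.

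Gene lists moved in DLD1 as well, and 1 list that had passed lost its call with the GC content and length trend removed. The removal shrank some medians, as for TGF-beta and YAP targets (0.35 to 0.19). It hardly moved others, with hypoxia targets going from 0.44 to 0.39, mesenchymal genes from 0.50 to 0.48 and NF-kB genes from -0.175 to -0.176. Ribosome biogenesis and MYC targets went from -0.23 to -0.30. Of 27 immediate early genes, 5 rose (12 adjusted over the list alone), with a median of 0.43 that was 0.30 with the GC content and length trend removed. FOSB rose by 1.25 and JUN by 1.10, and FOSB was low in DLD1 controls, at 1.26 to 1.72 CPM. The list had adjusted p 1.02e-11 in camera, and adjusted p = 0.192 with an estimated correlation. Of 19 glycolysis genes, 3 rose (13 adjusted over the list alone), including the glucose transporter gene SLC2A1, from 406 ± 107 to 709 ± 69.5 CPM, and PFKFB4 (0.70), a regulator of glycolysis. Their median of 0.41 was 0.27 with the trend removed. Their adjusted p was 3.81e-09, and adjusted p = 0.262 with an estimated correlation. Hypoxia (HIF) targets rose in 1 of 26 (13 up and 1 down adjusted over the list alone), namely ANGPTL4, with adjusted p 6.56e-08, and adjusted p = 0.223 with an estimated correlation. TGF-beta and YAP targets rose in 3 of 22 (9 adjusted over the list alone), with CYR61 at 0.73 and ANKRD1 at 1.77. ANKRD1 lay near the floor in DLD1 controls, at 0.488 to 0.754 CPM. Camera gave the TGF-beta and YAP list adjusted p 3.56e-07, and adjusted p = 0.192 with an estimated correlation. Mesenchymal genes (EMT) rose in 2 of 18 (6 adjusted over the list alone), SNAI1 (1.13), a transcription factor of that transition, and the integrin gene ITGA5 (0.80). SNAI1 was low in DLD1, at 2.25 to 3.37 CPM in controls and 4.80 to 7.73 after lactate. ITGA5 stood at 46.6 to 71.6 and 98.0 to 109 CPM. VIM, the vimentin gene, lay near the floor at 0.595 to 2.66 and 0.986 to 1.39 CPM. Camera placed the mesenchymal list at adjusted p 0.00172, and adjusted p = 0.192 with an estimated correlation. Enterocyte differentiation genes rose in 3 of 14 (5 adjusted over the list alone), with the adhesion gene CEACAM1 at 0.97. Their adjusted p was 0.00172, and adjusted p = 0.192 with an estimated correlation.

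Other lists were lower in DLD1. NF-kB and inflammatory genes fell in 6 of 27 (8 adjusted over the list alone), the members CXCL8, CCL20, CXCL1, CXCL2, CXCL3 and CXCL5, with adjusted p 0.00431, and adjusted p = 0.333 with an estimated correlation. It was 0.0695 without DLD1 control 3. Of 35 genes of G2/M and mitosis 0 were called (21 lower adjusted over the list alone), with a median of -0.30 (-0.18 with the GC content and length trend removed), adjusted p 1.02e-11, and adjusted p = 0.223 with an estimated correlation. Ribosome biogenesis and MYC targets had 0 of 28 called (12 lower adjusted over the list alone) and adjusted p 2.96e-06, and adjusted p = 0.192 with an estimated correlation. DNA replication and G1/S genes had 0 of 33 called (0 adjusted over the list alone) and adjusted p 0.00109, and adjusted p = 0.433 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 0 of 47 called (1 lower adjusted over the list alone) and adjusted p 0.00938, and adjusted p = 0.632 with an estimated correlation. It was 0.478 without DLD1 control 1, 0.313 without control 3 and 0.295 without lactate 1. Endoplasmic reticulum chaperones had 0 of 19 called (2 lower adjusted over the list alone) and adjusted p 0.0103, and adjusted p = 0.407 with an estimated correlation. Without control 3 it was 0.0695. Heat shock response genes had HSPA6 up of 16 (1 up and 7 down adjusted over the list alone), a median of -0.25 and a mean of 0.20. As a list they had adjusted p 0.0308 downward, and adjusted p = 0.333 with an estimated correlation. It was 0.0907 without control 3 and 0.0706 without lactate 2.

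A further pair of lists passed in DLD1 and was lost in places. Epithelial genes had 0 of 20 called (0 adjusted over the list alone), with a median of 0.23, adjusted p 0.0308, and adjusted p = 0.420 with an estimated correlation. It was 0.0699 without DLD1 control 2, 0.100 without lactate 1, 0.0553 without lactate 3 and 0.201 with the GC content and length trend removed. The MondoA targets had TXNIP up of 8 (2 adjusted over the list alone), adjusted p 0.0308, and adjusted p = 0.192 with an estimated correlation. It was 0.0963 without control 3 and 0.0510 without lactate 2. Of the 37 lists, 17 passed in SW480 and 15 in DLD1 in camera, 20 and 12 in fry, and 0 and 0 with an estimated correlation. Removing the GC content and length trend gave 17 and 17 in camera. In SW480 this added fatty acid synthesis (adjusted p 0.0172) and lost the MondoA targets (0.0663). In DLD1 it added cytosolic ribosomal proteins (adjusted p 0.0400), the secretory lineage (0.0394) and amino acid and glutamine metabolism (0.00425), and lost epithelial genes.

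**Figure D3:**
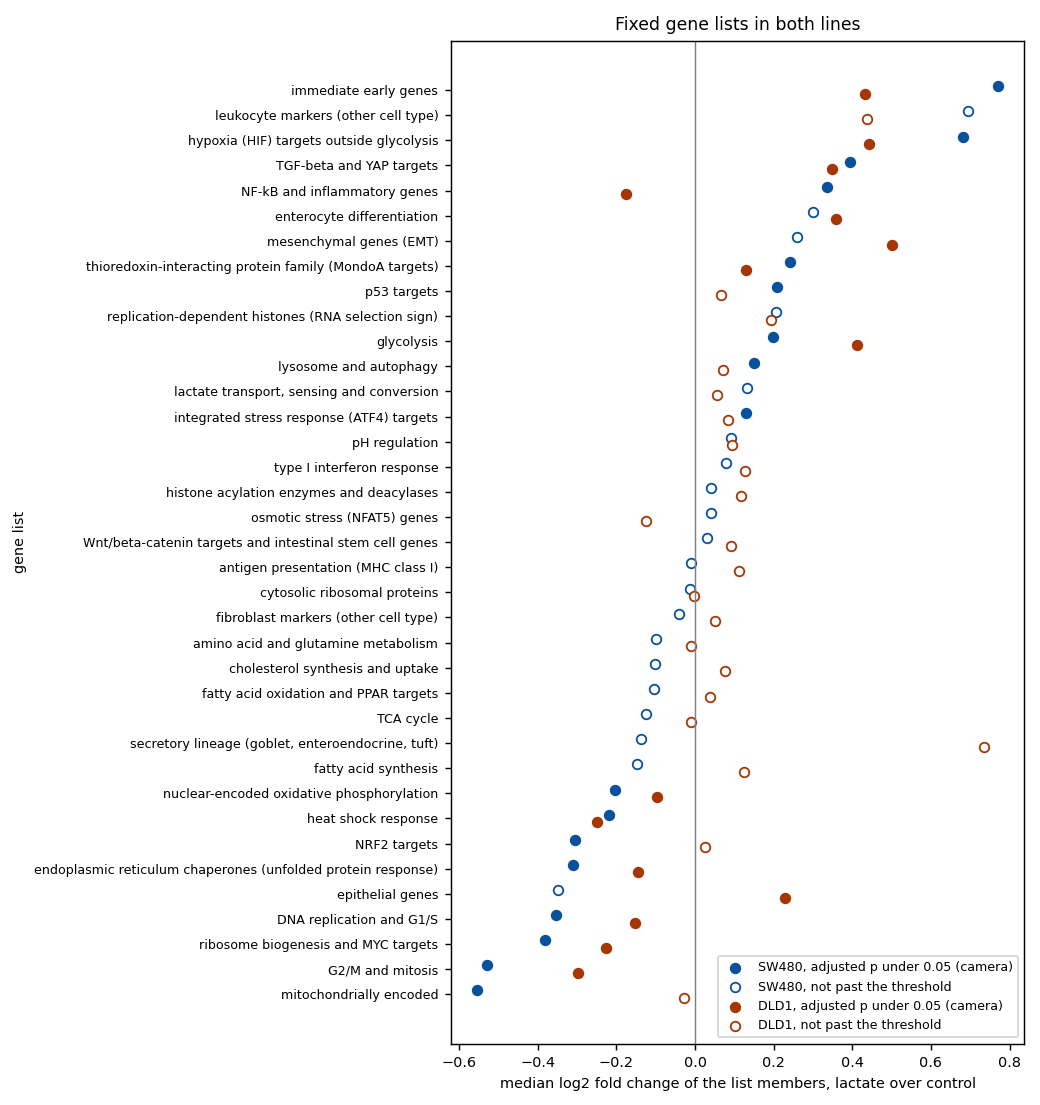
Median log2 fold change (lactate over control, horizontal axis) of each tested gene list (vertical axis) in SW480 and DLD1, filled where camera's adjusted p was under 0.05. Immediate early genes had medians of 0.77 and 0.43, and G2/M and mitosis genes -0.53 and -0.30.

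The next comparison asked which genes responded in both lines. HSPA6, ANGPTL4, SNAI1, ALDOC, TSC22D3, TXNIP, FGFR3, CTGF, AQP3 and SLC2A1 rose in both and had the largest smaller fold change of the 2 lines. TSC22D3, a glucocorticoid-induced regulator, rose by 1.59 in SW480 and 0.93 in DLD1. TXNIP, a glucose-responsive inhibitor of thioredoxin, rose by 0.95 and 0.89, the water and glycerol channel gene AQP3 by 0.97 and 0.81, and the receptor gene FGFR3 by 0.89 and 0.98. In SW480 the call of FGFR3 was lost without control 1 (adjusted p 0.0530) and without lactate 2 (0.0547). AMD1 changed by -0.46 and -0.67 and was past the threshold in 6 of the 12 fits that left out 1 library in SW480 and in 2 of 12 in DLD1. With the GC content and length trend removed it was called in both, with log2 -0.46 and -0.41. In SW480 its adjusted p was 0.138 without control 1, 0.102 without control 3, 0.104 without lactate 1, 0.138 without lactate 2, 0.0959 without lactate 3 and 0.0505 without DLD1 lactate 3. Apart from HSPA6, the calls of these genes in DLD1 depended on single libraries as given above.

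The lists shared 22 genes that rose, against 4.03 for independent lists (Fisher's exact test, p = 1.49e-11), and 1 that fell, against 0.447 (exact p = 0.369). Both lists came from 1 fit with 1 spread per gene, so a gene of low spread can be called in both lines without a shared response. The lists are therefore not independent, and this p does not measure a shared response. With each line fitted alone 1 gene was shared. The total of 23 was 14 without SW480 control 1, 12 without control 2, 9 without control 3, 11 without lactate 1, 8 without lactate 2 and 9 without lactate 3. It was 2 without DLD1 control 1, 71 without control 2, 694 without control 3, 3 without lactate 1, 5 without lactate 2 and 6 without lactate 3. With the GC content and length trend removed it was 294. Of the 2183 genes called in SW480, 1552 (71.1%) had the same sign in DLD1. Across all 17572 genes the fold changes of both lines had Pearson's r 0.0585 and Spearman's rho 0.140, and across 10048 genes with at least 5 CPM in both lines r 0.326 and rho 0.253, a set chosen after the data were seen. Without SW480 lactate 1 the r over all genes was -0.0122, and without SW480 control 2 it was 0.0965. Genes are not independent replicates.

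The last lactate comparison asked where the lines responded differently, as DLD1 minus SW480. Chemokine genes differed in direction: CCL20 rose in SW480 and changed by -1.09 in DLD1, a difference of -2.59 ± 0.26, and CXCL3 and CXCL8 differed by -1.44 ± 0.15 and -2.21 ± 0.31. CYP4F12, a cytochrome P450 gene, fell in SW480 (-1.39) and rose in DLD1 (1.10). MCL1, which encodes a protein that blocks apoptosis, rose from 2336 ± 444 to 7031 ± 841 CPM in SW480 and stood at 204 ± 26.8 and 202 ± 8.74 CPM in DLD1, a difference of -1.60 ± 0.20. PHLDA1 differed by -1.55 ± 0.19, CXCL1 by -1.02 ± 0.13 and IRS1, an adaptor of insulin signalling, by 1.20 ± 0.16. The call of CXCL8 in SW480 was lost without SW480 control 1 (adjusted p 0.0561).

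For the difference 128 genes were called in edgeR's quasi-likelihood test, 57 higher and 71 lower in DLD1, with adjusted p 9.04e-04 for CCL20, 0.00374 for MCL1 and 0.00797 for CXCL8. These calls and those of CXCL3, PHLDA1, CYP4F12, CXCL1 and IRS1 held without any 1 of the 12 libraries. The count was 9 without SW480 control 1, 10 without control 3, 238 without lactate 1, 19 without lactate 2 and 61 without lactate 3. It was 54 without DLD1 control 1, 596 without control 2, 1508 without control 3, 36 without lactate 1, 30 without lactate 2 and 11 without lactate 3. Removing the GC content and length trend gave 1323, and without a filter there were 837 (463 higher, 374 lower in DLD1). A list test of the difference, added after the data were seen, placed NF-kB and inflammatory genes lower in DLD1 (median -0.77, 7 of 27 called, adjusted p 6.28e-11, and adjusted p = 0.161 with an estimated correlation). Mitochondrially encoded genes stood higher (median 0.55, 3 of 13 called, adjusted p 6.12e-07, and adjusted p = 0.271 with an estimated correlation). In all 10 lists passed in camera and 0 with an estimated correlation.

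**Figure D4:**
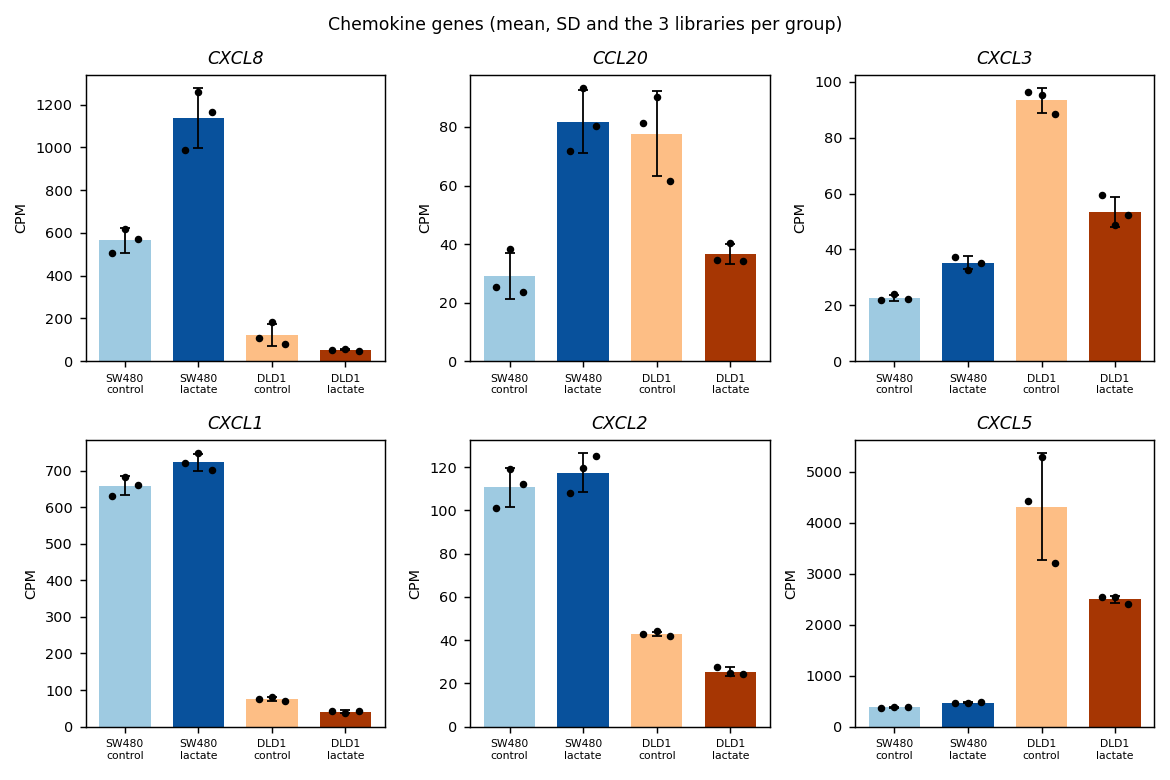
CPM (vertical axes, from 0) of 6 chemokine genes in the 4 groups, with 1 point per library, bars at the mean and error bars of 1 SD (n = 3). CXCL8 went from 565 to 1138 CPM in SW480 and from 124 to 53.9 CPM in DLD1.

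The control libraries described the lines before treatment. DLD1 controls expressed the epithelial genes CDH1 (680.3 ± 50.6 CPM) and EPCAM (686 ± 18.5), the intestinal transcription factor gene CDX2 (135 ± 40.0) and the stem cell gene LGR5 (38.7 ± 8.44). In SW480 controls these stood at 1.48 ± 0.133, 0.988 ± 0.189, 0.127 ± 0.153 and 0.115 ± 0.134 CPM. VIM, the gene of the mesenchymal filament vimentin, stood at 1535 ± 84.1 CPM in SW480 and 1.71 ± 1.04 in DLD1. KRT20, a keratin gene of differentiated intestine, stood at 0.798 ± 0.119 CPM in DLD1 and had a count of 0 in all 3 SW480 controls. Such low levels of CDH1 and EPCAM beside high VIM are unusual for a colon carcinoma line. Not all epithelial genes were low in SW480 controls. KRT8 stood at 1224 to 1440 CPM, KRT18 at 674 to 813 and DSP at 72.9 to 84.0, whereas ELF3 stood at 3.94 to 4.15. The identity of the cells in the libraries labelled SW480 could not be tested from the counts, so every SW480 result here rests on the labels. Of 20 epithelial genes 20 were higher in DLD1, as were 35 of 35 genes of G2/M and mitosis and 22 of 25 of cholesterol synthesis and uptake, whereas 13 of 18 mesenchymal genes and 24 of 27 immediate early genes were lower. In edgeR's quasi-likelihood test 12448 of 17572 genes were called, 5902 higher and 6546 lower in DLD1, and 7577 at least 2-fold (3210 higher, 4367 lower). The list tests of the lines were added after the data were seen, and the adjusted p was 4.35e-11 for epithelial genes, 5.14e-10 for G2/M, 5.00e-08 for cholesterol, 1.15e-04 for mesenchymal and 5.23e-06 for immediate early genes. In the same order the lists had adjusted p = 0.0513, 0.186, 0.0513, 0.0513 and 0.229 with an estimated correlation.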

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

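The tests of DLD1 control 2 and of the chemokine genes were written after these patterns had been seen but before the tests were run, and the correction for GC content and length was chosen after the result was seen.

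A set of 31 named genes had lactate effects that differed between the lines in edgeR's test of the difference itself. As DLD1 minus SW480 on the log2 scale, the chemokine genes differed by -2.59 (CCL20), -1.44 (CXCL3), -2.21 (CXCL8), -1.11 (CXCL5), -1.02 (CXCL1) and -0.84 (CXCL2). Genes whose lactate effect was higher in SW480 were ANKRD37 (-2.08), NDRG1 (-1.77), MCL1 (-1.60), PHLDA1 (-1.55), ARG2 (-1.41), CA12 (-1.05), HK2 (-0.99), TNFAIP3 (-0.86), KLF6 (-0.83) and NPC1 (-0.72). The effect was higher in DLD1 for CYP4F12 (2.49), AKR1B10 (2.18), FOS (1.29), IRS1 (1.20), PLK1 (1.09), NCOA5 (1.08), AGR2 (1.04), LSS (1.03), AXIN2 (0.94), KIF20A (0.90), MCM3 (0.79) and SCD (0.72). AKR1B10 lay near the floor in DLD1, at 0.293 to 0.900 CPM, and CYP4F12 was low in SW480, at 0.711 to 2.37 CPM. The mitochondrially encoded COX3, COX2 and ND1 differed by 0.85, 0.73 and 0.64. All 31 kept their sign without each library. Past the threshold were 8 without SW480 control 1, 29 without control 2, 8 without control 3, 29 without lactate 1, 9 without lactate 2, 23 without lactate 3, 20 without DLD1 control 1, 17 without DLD1 lactate 1, 13 without lactate 2 and 8 without lactate 3. CCL20, CXCL3, CXCL1 and CXCL8 held in all 12 of these fits, whereas CXCL2 held in 7 and CXCL5 in 5. Their adjusted p was 0.0767 and 0.0782 (CXCL2, CXCL5) without SW480 control 1, 0.0599 and 0.0599 without control 3, 0.0617 and 0.0530 without lactate 2, 0.0578 and 0.0542 without DLD1 lactate 2 and 0.0697 and 0.0697 without lactate 3. CXCL5 also had 0.0515 without DLD1 control 1 and 0.0607 without lactate 1.

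In SW480 the rise of CXCL5 was not called in the reported fit but was with the GC content and length trend removed (log2 0.39, adjusted p 9.10e-04), with the line fitted alone (0.00169), without a filter (just under 0.05), without DLD1 control 2 (0.0181) and without DLD1 control 3 (0.0205). CXCL1 was called there with the trend removed (log2 0.27, adjusted p 0.0390).

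Regroupings of the libraries within the lines bear on the 128 genes of this difference. Of 100 splits drawn, the real one included, 6 gave as many genes, with a highest other count of 2001, so chance was not excluded. All 5 others kept the SW480 libraries in their true groups, of which there were 11, whereas the 88 that regrouped them gave at most 0. Some of these counts were several times the real one. These 11 splits set the whole lactate effect of SW480 against regrouped DLD1 libraries, so that effect is part of their counts, and what else raises them was not tested.

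The chemokine pattern, a fall in DLD1 set against a rise in SW480 or none called in the reported fit, was weighed first. With DLD1 fitted alone the falls were not called (adjusted p 0.187 to 0.313). Without DLD1 control replicate 2, 6 of the 6 genes kept an adjusted p under 0.05 for the difference. CXCL2 and CXCL5 lost it without other libraries as given above. Leaving that library out also raised the SW480 calls from 2183 to 4347 with the SW480 libraries unchanged, so kept calls say little about it. The difference went from -2.21 to -1.82 for CXCL8 and from -1.11 to -0.94 for CXCL5. It was -2.48 for CCL20, -1.425 for CXCL3, -0.98 for CXCL1 and -0.82 for CXCL2. These sizes argue against that library as the whole cause, though part of the CXCL8 and CXCL5 differences rested on it. Under both other scalings 6 of the 6 also kept an adjusted p under 0.05 for the difference. These scale whole libraries and hardly moved it (CCL20 -2.62 and -2.57, against -2.59). They could not have removed the calls, so they decide nothing about normalization. With the GC content and length trend removed the same 6 were called for the difference. A response that differs between the lines stays open as a hypothesis and was not tested apart from other differences between the cultures. Reads shared among CXCL1, CXCL2 and CXCL3 could blur those 3 genes, but not CXCL8 or CCL20, and were not tested.

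The second pattern was DLD1 control 2, whose log2 difference from the other 2 controls had an SD of 0.537. A trend along GC content removed 56.0% of that variance. The SD stayed at 0.357, above the 0.261 of the most variable SW480 or DLD1 lactate library. The GC content was that of transcripts and not of the sequenced fragments, so removing its trend need not remove all of such a bias. DLD1 control 3, which is part of the comparison, also differed from its group (SD 0.442), so the leftover spread is not that of control 2 alone. The test therefore cannot decide whether GC content bias was the whole cause. A trend along transcript length removed 18.7% of the variance and left an SD of 0.484. The same limits hold there, so transcript length bias as the whole cause is not decided either. Cells or RNA of the other line in the library are argued against by 85 genes abundant in SW480 and near 0 in lactate-treated DLD1, whose median excess was 0% of the SW480 level. No biological explanation was tested, and the cause of the pattern stays open.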

How the results depend on the processing

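The correction for GC content and length and the correlation over genes expressed in both lines were chosen after the data were seen; the other alternatives were set before. Counts within 1.5 times the reported value are not listed. In SW480 the 2183 genes became 4783 with the line fitted alone, 4862 with the GC content and length trend removed and 515 at 2-fold or more. In DLD1 the 67 became 855 without a filter, 684 with DESeq2, 184 with replicate blocks, 1 with the line fitted alone, 561 with the trend removed and 31 at 2-fold. The 128 of the difference became 837, 719, 274, 1323 and 79 under no filter, DESeq2, blocks, trend removal and 2-fold. The 23 shared genes became 224, 261, 68, 1, 294 and 6 under no filter, DESeq2, blocks, each line alone, trend removal and 2-fold. The 12448 between the lines became 7577 at 2-fold. The 17 and 15 lists became 0 and 0 with an estimated correlation. The correlation of 0.0585 was 0.00961 without a filter, 0.206 with each line alone and 0.326 over expressed genes. The smaller counts at 2-fold follow from the added threshold. For the other settings the cause was not tested.

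Leaving out 1 library at a time gave 689 to 4347 genes in SW480, 3 to 3791 in DLD1, 9 to 1508 for the difference, 2 to 694 shared genes and a correlation of -0.0122 (reversed, without SW480 lactate 1) to 0.0965. Of the fits of named genes that left out a library, 1758 kept their side of the threshold in SW480, 180 lost a call and 6 gained one, against 1701, 198 and 45 in DLD1. The correlation of same-numbered control and lactate deviations ran from -0.0708 to 0.173, against -0.227 to 0.133 for differently numbered ones. With 3 libraries centred on each group mean, these values cannot decide whether replicate numbers paired the libraries. With 3 libraries per group, changes near 1.5-fold were mostly missed in simulated data (32.8% and 34.3% recovered), so a gene not called may still have changed. The simulation gave both lines the same spread, so it does not show the recovery among the more variable DLD1 controls.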

Other observations

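The 2 tests of HSPA6 below were chosen after the result was seen, and how the test of near-identical HSP70 genes and the splits for the shared genes are read was set again after they had been run, whereas the splits of the libraries were set before they were run.

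Several lists in SW480 held members that moved apart, with no call for the list in camera. In fry 2 of them passed, cholesterol synthesis and uptake downward (adjusted p 0.0319) and mesenchymal genes upward (0.00170). Among 25 genes of cholesterol synthesis and uptake, 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p 0.166). INSIG1, which restrains cholesterol synthesis, rose by 0.74, whereas the lanosterol synthase gene LSS changed by -0.68. Of 23 Wnt/beta-catenin targets and intestinal stem cell genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p 0.599), with SOX9 at 0.83, the adhesion gene CD44 at 0.69 and the feedback inhibitor AXIN2 at -0.93. Of 24 type I interferon response genes 3 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p 0.318), with IFI44L at -0.79. Of 18 mesenchymal genes 5 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p 0.0981). ITGA5 rose by 1.35 and CDH11 changed by -1.05. Of 20 epithelial genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p 0.934), with a median of -0.35 and a mean of 0.01.

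In camera, lists tied to a direct effect of lactate gave no call, although single members were called in SW480. Osmotic stress (NFAT5) genes had adjusted p 0.846 in SW480, where AKR1B1, the aldose reductase gene, changed by -0.64 and the taurine transporter gene SLC6A6 rose by 0.32, and 0.831 in DLD1. SLC6A6 held only without SW480 lactate 3, DLD1 control 2, DLD1 control 3 or DLD1 lactate 1, with adjusted p of 0.0559 to 0.175 without each other library, 0.0910 without a filter and 0.0747 with replicate blocks. For pH regulation the values were 0.475 and 0.555. In SW480 the carbonic anhydrase genes CA12 and CA9 rose by 0.56 and 0.66, and the anion exchanger gene SLC4A2 changed by -0.55. CA9 and SLC4A2 had adjusted p 0.187 and 0.0962 without SW480 control 1, 0.0971 and 0.0663 without control 3 and 0.124 and 0.0951 without lactate 2. CA9 also had 0.0892 without lactate 1 and 0.0521 without DLD1 lactate 1, and SLC4A2 0.0925 without SW480 lactate 3. Histone acylation enzymes and deacylases had 0.355 and 0.238 in camera, and 0.0550 and 0.0406 in fry, where the list passed in DLD1. In SW480 the histone deacetylase genes HDAC5, HDAC6 and HDAC3 rose by 0.97, 0.52 and 0.33. Without SW480 control 1 HDAC5 and HDAC6 had adjusted p 0.0569 and 0.0556. HDAC3 held only without SW480 lactate 3, DLD1 control 2 or DLD1 control 3, with 0.0559 to 0.176 otherwise, and had 0.0956 without a filter and 0.0557 with replicate blocks.

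Markers of other cell types gave camera adjusted p of 0.599 and 0.259 for fibroblasts and 0.303 and 0.0529 for leukocytes, in the order SW480 and DLD1. In SW480 the collagen gene COL1A1 rose from 21.6 ± 1.99 to 50.8 ± 1.61 CPM, the fibrillin gene FBN1 by 0.47 and CD68, a lysosomal protein gene of macrophages, from 40.6 ± 10.1 to 99.5 ± 11.7 CPM. COL1A1 and CD68 held without any 1 of the 12 libraries. FBN1 had adjusted p 0.0879 without SW480 control 1, 0.0528 without control 2, 0.0501 without lactate 3 and 0.0567 without a filter. Replication-dependent histones gave 0.734 and 0.259. In DLD1, SCD, a fatty acid desaturase gene, rose by 0.72 (adjusted p 0.00986).

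HSPA6 rose in both lines while most other heat shock genes did not. The 15 other members of the list had a median log2 fold change of -0.23 in SW480 and -0.32 in DLD1, with 3 and 4 above 0. Most of the counted members thus did not rise with HSPA6. This restates the pattern, seen before the test was written, so it is no separate test of a general heat shock response. Reads from near-identical HSP70 genes stay open: 0 of the other HSP70 genes rose in both lines by 10% or more of the rise of HSPA6. HSPA2 was higher by 4.23 CPM in SW480 (adjusted p 0.0269), above that bound, and by 0.412 CPM in DLD1 (adjusted p 0.666). Other rises under the bound were seen in both lines, and HSPA1A held 4 counts and HSPA1B 295 over all libraries, so reads of that pair could have been lost in counting; no biological explanation was tested.

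The 2183 genes in SW480 were matched by 1 of the 10 splits of its 6 libraries, the real one, with a highest other count of 0. For the 67 in DLD1 it was also 1 of 10, with a highest other of 0, and for the 12448 between the control groups 1 of 10, with a highest other of 0. These splits are too few for a share under 0.05. For the 23 genes shared in direction 1 of 100 drawn splits, the real one, gave as many, with a highest other of 0, but each other grouping within a line called 0 genes, which fixes their shared count at 0, so this comparison decides nothing about chance. The correlation of fold changes between the lines was as large in 9 of 100 splits for Pearson's r (highest other 0.130) and in 18 of 100 for Spearman's rho (highest other 0.334).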
